A study of Rattus norvegicus with 6 samples.

How the data were processed

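RNA was measured by poly(A)-selected, strand-marked (dUTP) paired-end RNA sequencing in 6 libraries of rat bone marrow mesenchymal stem cells, given the cell line name SCSP-402. The labels put 3 libraries in an untreated group and 3 in a group stimulated with lipopolysaccharide (LPS), a bacterial cell wall component that activates toll-like receptor 4. In both groups the stem cells were co-cultured with BV2, a mouse microglial cell line. The labels place all 6 libraries in 1 batch. Nothing in them says whether the replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

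The analysis started from 1 deposited table of 19266 genes, each with an estimated count and an FPKM value per library. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used with the rat build mRatBN7.2. The annotation release, the strand setting and the way the counts were derived are not given in the sources used here. Per the file headers, the FPKM columns hold fragments per kilobase per M fragments, as the authors scaled them. The deposited count columns were treated as estimated (expected) counts that had not been normalized. Their values are whole, but between 1 and 40 from 31.9% to 32.9% of them were multiples of 4, where 25% would be by chance. 1 sequenced fragment was therefore taken to be worth about 4 count units. Totals ran from 77.4 M to 82 M units per library, or 19.3 M to 20.5 M fragments after division by 4. Between 16623 and 16948 genes had a count above 0 in each library. Expected counts are rounded before a count test, which changed nothing here because the deposited values were whole. Strand use in the counting is unknown, so overlapping antisense genes are uncertain, as are genes with close copies such as RT1 class I, Mt1 and Mt2A, Gbp and Cxcl family members.

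Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 11559 in all. The design fixed before the data were examined called for limma on log2(FPKM + 1), or for edgeR if the table held raw counts. It held whole counts of unknown derivation, so whether that condition was met is uncertain. They were taken to meet it. edgeR's quasi-likelihood test (version 4.0.16, trimmed-mean normalization factors, glmQLFit and glmQLFTest) therefore gave the results, with the group as its only term. Benjamini-Hochberg adjustment covered all tested genes, with a threshold of 0.05. Every adjusted p of a single gene comes from this test unless another tool is named. Means ± SD are of the deposited FPKM over 3 libraries. Fold changes and their standard errors come from the fit to the counts, with the standard error taken as the size of the log2 fold change divided by the square root of F.

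26 gene lists with 538 symbols were fixed before the data were examined. 497 of the symbols were in the table and 369 were tested. Symbols such as Gapdh and Mx1 were not analysed here, and some genes that the naming rule takes are left out of the text. The 22 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) on log2(FPKM + 1), with a preset correlation between genes of 0.01 and adjustment over the lists. camera was also run with the correlation estimated for each list. The rule for named genes was fixed at the same time. It takes Tnfaip6, the 10 genes with the greatest rise and the 10 with the greatest fall among those past the test with a mean FPKM of at least 5 in the higher group, separate groups and a proper symbol, up to 4 called members of each list with the largest change and a mean FPKM of at least 1 in either group, and the tested members of the hyaluronan list. Where fewer than 2 members of a list passed, its most abundant members fill up to 2. The Tnfaip6 FPKM values were also compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

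Pathway annotation in the deposited table was tested by Fisher's exact test (scipy 1.17.1) among 4859 tested genes with an annotation, over 232 pathways of 10 to 300 such genes in both directions, leaving out disease and overview maps by number. The test was repeated with the genes of the fixed lists left out, over 230 pathways among 4568 genes. Statistics ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. The gene test was tested on simulated counts drawn from the means and library sizes of these 11559 genes, with 200 genes changed. In that simulation it recovered 72% of the genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 3- or 4-fold, and 5.18% of its calls were false. All genes were given the same dispersion, and 200 were changed, where 4524 were called in the data. A library lying apart from its group, as untreated replicate 1 did, was not simulated. The rates therefore need not hold for the real libraries. In the camera simulation a raised list of 25 genes was called and 0 of 20 unchanged lists were. Its genes were drawn independently, so it cannot show how correlation between genes affects the set test.

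No pair of replicates agreed within counting noise, as the chi-square per degree of freedom between replicates, on counts divided by 4, ran from 4.32 to 19.5. The alternatives tried were limma on the FPKM values with pseudocounts of 0.1, 1 and 5, other filters, scalings and variance models, DESeq2 1.42.0, a replicate block, each library left out in turn, and other set tests. Those added after the data were seen were counts divided by 4, protein-coding genes alone, camera on the counts, and library sizes without the 50 most abundant genes. limma with a pseudocount of 1 was the design's test for a table without raw counts. It was made an alternative after the table was seen.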

Results

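The series asked how bone marrow mesenchymal stem cells restrain the activation of microglia, and its title names the rise of TSG-6 in the stem cells under LPS. The comparison was between 3 libraries of rat mesenchymal stem cells co-cultured with the mouse microglial line BV2 and stimulated with LPS, and 3 libraries of the same co-culture without LPS. The untreated libraries held 80.8 M, 77.4 M and 80.7 M count units and the LPS libraries 80.2 M, 79.1 M and 82 M, so depth differed little. On the first principal component, which carried 71.5% of the variance, the LPS libraries lay between 25.4 and 30.1 and untreated replicates 2 and 3 at -36.1 and -38.0. Untreated replicate 1 lay between them at -11.3. Ribosomal RNA genes took 0.158% ± 0.055 of the counts in the untreated and 0.733% ± 0.615 in the LPS libraries (SD, n = 3), with 1.36% in LPS replicate 1. Genes of the mitochondrial genome took 2.69% ± 0.141 and 3.04% ± 0.154.

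With LPS, the stem cell co-cultures held more RNA of chemokines, NF-kB targets, MHC class I genes, cell cycle genes and glycolytic genes. They held less of contractile genes and of most tested bone and cartilage markers. These directions rest on camera with a preset correlation, as the lists had adjusted p from 0.269 to 0.453 with an estimated correlation, and the cartilage list was too short for a set test. All 11 tested chemokine and colony-stimulating factor genes, of 22 in the table, and 33 of 35 cell cycle genes rose, while 15 of 20 contractile genes fell. Tnfaip6, which encodes the secreted hyaluronan-binding protein TSG-6, was higher with LPS. Its FPKM was 13.1 ± 1.85 in untreated and 18.6 ± 0.418 in LPS co-culture (SD, n = 3), a 1.37-fold difference. The untreated libraries stood at 15.2, 11.6 and 12.6 FPKM and the LPS libraries at 18.8, 18.8 and 18.1, so all 3 LPS values lay above all 3 untreated values. The gene (ENSRNOG00000050792) lies on the plus strand of chromosome 3 from 36502188 to 36521649 in mRatBN7.2. Its log2 fold change was 0.45 ± 0.097 (SE), with an adjusted p of 0.00696 by edgeR, and the exact two-sided permutation test of the FPKM values gave p = 0.1, the smallest it allows. A larger log2 fold change was found for 1279 of the 11559 tested genes.

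Other genes that make, bind or degrade hyaluronan moved as well. Of the 12 tested members of the list of hyaluronan and TSG-6 partners, 7 rose and 2 fell, and 7 rose and 3 fell when adjusted over the list alone. These counts include Tnfaip6 itself, among the genes that rose. The largest rise was that of Ptx3, a pentraxin that TSG-6 binds, from 6.06 ± 2.30 to 34.7 ± 1.66 FPKM (log2 fold change 2.47 ± 0.22 SE, adjusted p = 0.000133). The hyaluronan synthase Has2 rose 1.85-fold, the hyaluronan-binding proteoglycan versican (Vcan) 1.86-fold, and the hyaluronan-degrading factors Cemip and Cemip2 2.00-fold and 1.48-fold. The hyaluronan receptor Hmmr, also a gene of the mitotic spindle, rose 1.68-fold. Aggrecan (Acan), the large cartilage proteoglycan, fell from 133 ± 28.6 to 46.3 ± 1.96 FPKM. Thbs1 was 1.12-fold lower (adjusted p = 0.0216), a call that was lost in 10 of 22 alternatives. They included limma on the FPKM values (adjusted p = 0.147), limma with quantile normalization (0.331) and leaving out untreated replicate 2 (0.0521), LPS replicate 1 (0.0596) or LPS replicate 2 (0.0955). The hyaluronan receptor Cd44 stood at 46.3 ± 2.24 and 46.5 ± 2.08 FPKM (adjusted p = 0.591), Hyal1 at 1.55 ± 0.527 and 1.64 ± 0.316 FPKM, and Hyal2 at 21.4 ± 0.846 and 18.7 ± 2.35 FPKM (adjusted p = 0.0513). Hyal2 passed as lower in 9 of 22 alternatives, among them DESeq2 (adjusted p = 0.0234), quantile normalization (0.0358) and leaving out untreated replicate 1 (0.0252) or LPS replicate 2 (0.00965), with a range up to 0.158. The list did not pass camera (adjusted p = 0.106; adjusted p = 0.433 with an estimated correlation). It passed in 4 of 19 alternatives, which were leaving out untreated replicate 1 (0.0331), quantile normalization (0.0312), camera on the counts (0.00684) and fry (0.00361).

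**Figure D1:**
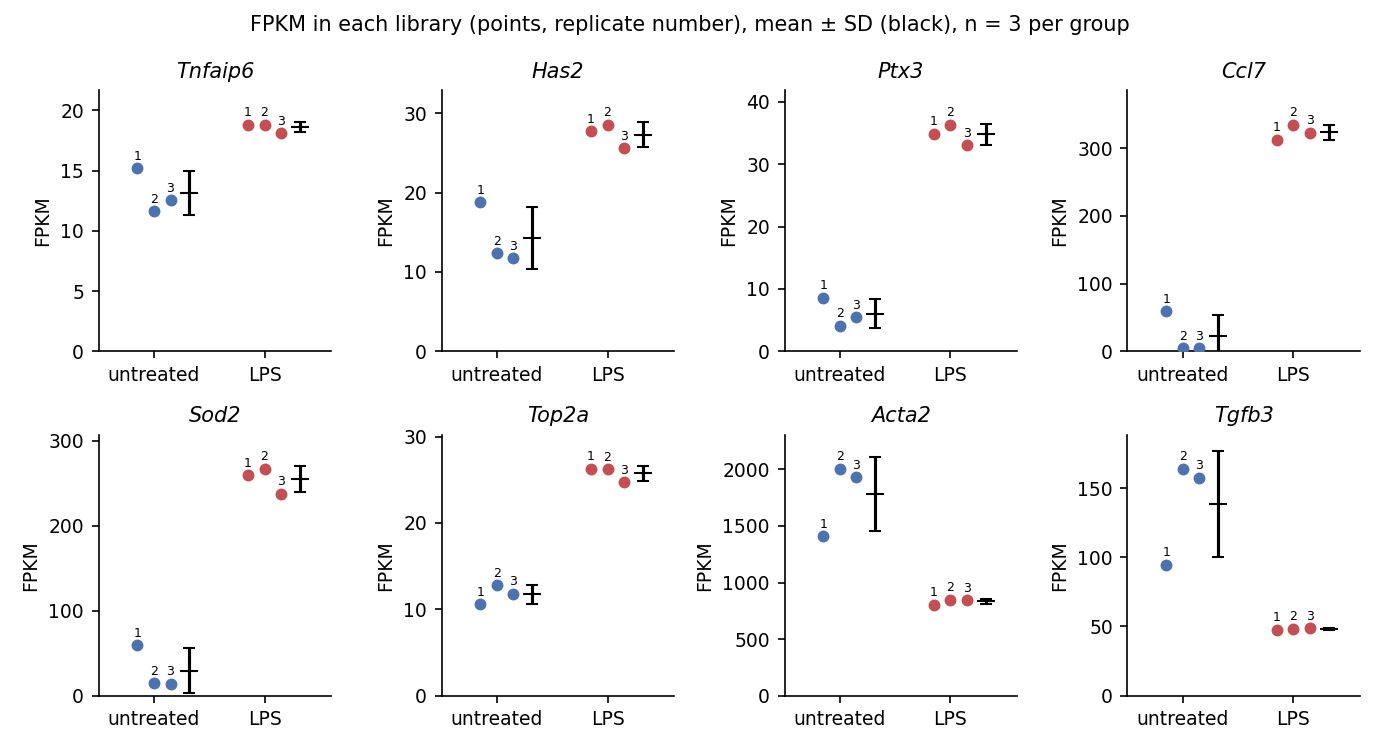
FPKM (y axis, linear from 0) of 8 named genes in the untreated and LPS co-culture libraries (x axis), with points numbered by replicate and black bars for the mean ± SD of 3 libraries. The LPS values of Tnfaip6 (18.1 to 18.8) all lie above the untreated values (11.6 to 15.2), and untreated replicate 1 is the untreated library nearest to the LPS group in each panel except that of Top2a.

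Over all genes, 2323 were higher and 2201 lower with LPS by edgeR, while 7035 of the 11559 did not pass. At least 2-fold changes were found for 300 of the higher and 197 of the lower genes. The higher genes made up 51.3% of the calls, against 63.3% with limma on the FPKM values as deposited, which called 2903 higher and 1685 lower. With quantile normalization the share was 44.7% (1996 higher, 2466 lower) and with library sizes without the 50 most abundant genes 44.2% (2019 and 2553), so which direction held the majority depended on the scaling. Groups were fully separate in FPKM for 53.3% of tested genes, where chance gives 10%. The greatest rises under the naming rule included the lipoprotein lipase inhibitor Angptl4 (0.525 ± 0.819 to 31.8 ± 5.25 FPKM), the stromelysin Mmp3 (1.44 ± 0.878 to 36.4 ± 4.47), the siderophore-binding protein Lcn2 (2.76 ± 4.70 to 59.1 ± 10.5), the guidance cue Ntn1 (0.429 ± 0.366 to 7.93 ± 0.526) and the protease inhibitor Slpi (0.694 ± 0.990 to 12.1 ± 2.58). Their untreated means depended on untreated replicate 1. Without it the fold rose from 57.6 to 528 for Angptl4, from 24.4 to 37.5 for Mmp3 and from 17.8 to 34.6 for Ntn1. Lcn2 then rested on 2 fragments in the untreated libraries, a ratio of 1380 with an exact 95% interval from 383 to 11400, and Slpi on 3 fragments, a ratio of 83.6 from 28.4 to 407. These intervals cover counting error only. The Lcn2 call (adjusted p = 0.0156) was lost without LPS replicate 2 (0.0568) and with DESeq2 (0.110).

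Among the greatest falls, Wscd2 fell from 6.0 ± 2.21 to 0.285 ± 0.0932 FPKM (log2 fold change -4.42 ± 0.35 SE, adjusted p = 9.69e-05) and the annexin Anxa8 from 8.64 ± 2.79 to 0.881 ± 0.0484. C1qtnf3, a secreted C1q and TNF-related protein, fell from 179 ± 43.6 to 23.0 ± 1.40 FPKM and was 8.05-fold lower. Ccdc3 was 7.73-fold lower, the carbonic anhydrase Car3 6.11-fold, the Wnt antagonist Frzb 5.42-fold and the calcium-binding protein Casq2 5.02-fold. Cilp, Igfbp5 and Capn6 were between 4.86-fold and 4.47-fold lower, with Cilp and Igfbp5 encoding a cartilage matrix protein and an insulin-like growth factor binding protein.

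Chemokines and colony-stimulating factors formed the list with the highest median. Of 22 members in the table, 11 were tested. All 11 tested members rose, also when adjusted over the list alone, with a median log2 fold change of 3.23. The filter admits a gene near 0 in untreated co-culture through its LPS values alone, as with Csf3, so this count leans towards rises. Below the filter, Cxcl10 and Cxcl9 were lower with LPS (0.179 to 0.0385 and 0.026 to 0.0123 FPKM). Ccl5 and Cxcl2, also below it, were higher (0 to 0.339 and 0 to 0.448 FPKM). Ccl7, which attracts monocytes, rose from 22.8 ± 31.4 to 323 ± 11.2 FPKM, and Ccl20 from 4.41 ± 6.13 to 63.3 ± 7.88. The neutrophil attractants Cxcl6 and Cxcl3, whose reads could be shared with related genes, rose from 3.28 ± 5.45 to 91.5 ± 13.2 and from 0.566 ± 0.738 to 12.8 ± 1.10 FPKM. Csf3, the granulocyte colony-stimulating factor, rose from 0.149 ± 0.258 to 4.80 ± 0.586 FPKM. The list passed camera (adjusted p = 4.4e-06), with an adjusted p of 0.388 with an estimated correlation. The large untreated SDs came from untreated replicate 1, which held 59.1 FPKM of Ccl7 where replicates 2 and 3 held 4.55 and 4.87. Without it the fold rose from 13.7 to 66.0 for Ccl7, from 13.9 to 68.8 for Ccl20, from 27.0 to 696 for Cxcl6 and from 21.7 to 85.0 for Cxcl3, and Csf3, at 0 counts in the other untreated libraries, was at least 87.3-fold higher, taking 3 fragments over both as the floor. DESeq2 did not call Cxcl6 (adjusted p = 0.0729) or Csf3 (0.0776).

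Of the 8 tested inflammatory cytokines, 4 rose and 1 fell, and 4 rose and 2 fell when adjusted over the list alone. Il6 rose from 5.57 ± 5.01 to 33.0 ± 5.02 FPKM and Il1a from 0.725 ± 1.19 to 8.44 ± 0.697, while the alarmin Il33 fell from 8.77 ± 2.33 to 2.61 ± 0.0706. Lif rose 1.58-fold. Il1b, Tnf and Il10 were below the expression filter and not tested, at mean FPKM of 0.0145, 0.0179 and 0.0351 in untreated and 0.464, 0.0507 and 0.0105 in LPS co-culture. All 3 LPS libraries lay above all 3 untreated libraries for Il1b. The list did not pass camera (adjusted p = 0.473). Without untreated replicate 1 the fold rose from 5.74 to 11.8 for Il6 and from 11.2 to 206 for Il1a. The Il1a call (adjusted p = 0.0265) was lost without any one of the LPS libraries (up to 0.0708) and with DESeq2 (0.0574), and that of Lif (0.0264) without untreated replicates 2 or 3 or LPS replicates 1 or 3 (up to 0.0825).

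Targets and feedback regulators of NF-kB, the transcription factor activated through toll-like receptors, rose in 19 of 23 cases with none lower, and in 20 when adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, rose from 29.4 ± 26.1 to 255 ± 15.3 FPKM. The NF-kB inhibitors Tnfaip3 (A20) and Tnip3 rose 3.16-fold and 16.3-fold, and the RNase gene Zc3h12a 3.11-fold. camera gave an adjusted p of 8.8e-07, and an adjusted p of 0.388 with an estimated correlation. Without untreated replicate 1 the fold of Sod2 rose from 8.4 to 17.1, and Tnip3 rested on 2 untreated fragments, with a ratio of 80.1 (exact 95% interval 21.9 to 665, counting error only). Of 23 tested components of toll-like receptor 4 signalling, 7 rose and 4 fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.534). Those that rose included the receptor Tlr2 (0.203 ± 0.162 to 2.77 ± 0.0918 FPKM), the inhibitory kinase Irak3 (3.06-fold), Map3k8 (2.21-fold) and Traf3 (1.49-fold). The fold of Tlr2 rose from 13.1 to 24.0 without untreated replicate 1.

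All 13 tested genes of MHC class I antigen presentation rose, also when adjusted over the list alone, with a median log2 fold change of 0.88. They included the immunoproteasome subunit Psmb9 (3.21-fold), the peptide-loading factor Tapbp (2.35-fold) and the class I genes RT1-A1 and RT1-A2 (2.57-fold and 2.51-fold), whose reads could be shared among RT1 copies. camera gave an adjusted p of 8.8e-07, and an adjusted p of 0.269 with an estimated correlation. Among 22 tested interferon-response genes, of 40 in the table, 11 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone. Isg15, Rsad2, Ifit1 and Ifit3 were below the filter, at mean FPKM of 0, 0, 0.031 and 0.073 in untreated and 0.0021, 0.012, 0.092 and 0.021 in LPS co-culture. Usp18 and Rtp4, also below it, were higher with LPS (0.269 to 0.873 and 0.134 to 0.508 FPKM). Ifitm3, which restricts virus entry, rose from 266 ± 42.9 to 448 ± 21.5 FPKM, while Gbp2, Irf7 and Bst2 rose from 1.21 ± 0.417, 1.24 ± 0.358 and 0.658 ± 0.410 to 2.35 ± 0.168, 2.32 ± 0.0995 and 1.76 ± 0.328 FPKM. The list passed camera (adjusted p = 0.00913), with an adjusted p of 0.438 with an estimated correlation, and did not pass among genes with an FPKM of at least 5 (0.118). The Bst2 call (adjusted p = 0.0258) was lost without untreated replicates 2 or 3 or LPS replicates 2 or 3 (up to 0.0836), its fold rose from 2.57 to 3.91 without untreated replicate 1, and the Irf7 call (0.0145) was lost without LPS replicate 1 (0.0508). MHC class II had 1 tested gene, the peptide-exchange factor subunit RT1-DMa, which rose 1.85-fold.

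Of 22 tested factors through which mesenchymal stem cells are known to act on immune cells, 13 rose and 3 fell, also when adjusted over the list alone. Stanniocalcin (Stc1) rose from 1.80 ± 1.68 to 16.2 ± 1.67 FPKM, hepatocyte growth factor (Hgf) from 0.921 ± 0.662 to 4.37 ± 0.0377 and galectin 9 (Lgals9) from 0.605 ± 0.709 to 2.98 ± 0.298. Tgfb3 fell from 139 ± 38.3 to 48.2 ± 0.509 FPKM. The list did not pass camera (adjusted p = 0.0512), and passed in 12 of 19 alternatives, among them the replicate block (0.0338), camera on the counts (0.0480) and leaving out untreated replicate 1 (0.00970), untreated replicate 2 (0.0454) or LPS replicate 2 (0.0375), with an adjusted p of 0.454 with an estimated correlation. Without untreated replicate 1 the fold rose from 8.70 to 18.6 for Stc1, from 4.58 to 7.66 for Hgf and from 4.74 to 14.2 for Lgals9. The Lgals9 call (adjusted p = 0.0251) was lost on leaving out any library other than untreated replicate 1 (up to 0.0717).

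Of 9 tested complement genes, 6 rose and 0 fell, and 7 rose when adjusted over the list alone. The proteases C1r and C1s rose from 67.0 ± 28.8 to 195 ± 4.33 FPKM and from 20.1 ± 17.8 to 98.0 ± 0.764, and the complement inhibitors Cd55 and Serping1 5.99-fold and 5.64-fold. camera gave an adjusted p of 0.00339, and an adjusted p of 0.269 with an estimated correlation. Without untreated replicate 1 the fold rose from 4.72 to 9.60 for C1s, from 5.99 to 9.87 for Cd55 and from 5.64 to 9.04 for Serping1. Among 18 tested genes of oxidative stress and metal binding, 6 rose and 4 fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.906). The metallothioneins Mt2A and Mt1, which could share reads, rose 8.72-fold and 6.75-fold, or 25.8-fold and 12.8-fold without untreated replicate 1. The cystine transporter Slc7a11 was 3.31-fold lower.

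Cell cycle genes formed the list with the smallest p by camera with the preset correlation. Of 35 tested, 33 rose and 0 fell, and 34 rose when adjusted over the list alone, with a median log2 fold change of 0.80. The near-uniform rise belongs to these chosen genes. Among 124 annotated cell cycle pathway genes outside the fixed lists, 44 rose (35.5%, background 23.0%) and 25 fell (20.2%, background 18.9%). The mitotic cyclin Ccnb2 rose from 8.14 ± 1.18 to 20.7 ± 0.160 FPKM, ribonucleotide reductase Rrm2 from 21.7 ± 1.16 to 48.1 ± 1.38, topoisomerase Top2a from 11.7 ± 1.09 to 25.8 ± 0.886 and the mitotic activator Cdc20 from 17.6 ± 1.46 to 38.0 ± 0.589. camera gave an adjusted p of 1.0e-15, and an adjusted p of 0.269 with an estimated correlation. In this list untreated replicate 1 lay on the far side of the other untreated libraries, as the called genes stood there at a median of -18.5% of the way from the mean of the other untreated libraries to the LPS mean.

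Genes of glycolysis and the hypoxia response rose in 18 of 23 cases with none lower, also when adjusted over the list alone. The vasoactive peptide gene Adm rose from 6.95 ± 4.08 to 39.9 ± 1.82 FPKM, the glucose transporter Slc2a1 from 33.1 ± 12 to 71.6 ± 3.55 and Ndrg1 from 23.2 ± 7.24 to 47.3 ± 1.97. Egln3, an oxygen-sensing prolyl hydroxylase, rose from 0.102 ± 0.164 to 1.51 ± 0.0847 FPKM. camera gave an adjusted p of 8.8e-07, and an adjusted p of 0.453 with an estimated correlation. Without untreated replicate 1 the fold of Adm rose from 5.56 to 8.36, and Egln3 rested on 1 untreated fragment, with a ratio of 176 (exact 95% interval 31.3 to 6970, counting error only). DESeq2 did not call Egln3 (adjusted p = 0.0616).

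Contractile genes and genes induced by TGF-beta fell in 15 of 20 cases, with 3 higher, and 15 fell and 4 rose when adjusted over the list alone. Smooth muscle actin (Acta2) fell from 1781 ± 326 to 833 ± 23.4 FPKM and connective tissue growth factor (Ccn2) from 1068 ± 109 to 519 ± 32.8. Smooth muscle myosin (Myh11) was 3.66-fold and Actg2 2.54-fold lower. camera gave an adjusted p of 9.7e-06, and an adjusted p of 0.269 with an estimated correlation.

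Among 29 tested collagens and other matrix genes, 15 fell and 9 rose, and 16 fell and 10 rose when adjusted over the list alone. Together they took 19.8% ± 0.863 of the counts in untreated and 15.4% ± 0.184 in LPS co-culture (SD, n = 3). Col6a3 fell from 160 ± 25.4 to 66.3 ± 4.45 FPKM, while the small proteoglycans decorin (Dcn) and lumican (Lum) rose from 119 ± 41.6 to 338 ± 13.9 and from 189 ± 50.3 to 385 ± 15.1, and fibulin 1 (Fbln1) rose 3.15-fold. The list did not pass camera (adjusted p = 0.0636) but passed as lower without untreated replicate 1 (0.00818) and with array weights (0.0244), with an adjusted p of 0.539 with an estimated correlation. Matrix proteases and their inhibitors rose in 12 of 18 cases with 2 lower, and in 14 with 2 lower when adjusted over the list alone. The gelatinase Mmp9 rose from 0.872 ± 0.771 to 9.61 ± 1.49 FPKM and the collagenase Mmp13 from 6.08 ± 2.84 to 22.7 ± 1.45, while the protease inhibitor Timp3 fell from 22 ± 2.83 to 7.96 ± 0.533. camera gave an adjusted p of 0.000728, and an adjusted p of 0.269 with an estimated correlation. The fold of Mmp9 rose from 10.6 to 21.6 without untreated replicate 1.

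In the unfolded protein and integrated stress response list, 12 of 21 genes fell and 6 rose, and 13 fell and 6 rose when adjusted over the list alone. Those with the largest falls are known targets of the transcription factor ATF4, an arm of the response that was not tested on its own. Atf3 fell from 19.2 ± 0.972 to 6.43 ± 1.72 FPKM, Atf5 from 139 ± 42.1 to 51.8 ± 5.33, and Chac1 from 66.5 ± 9.07 to 30.8 ± 6.62, while the log2 fold change of Trib3 was -1.14 ± 0.08 (SE). camera gave an adjusted p of 0.0191, and an adjusted p of 0.302 with an estimated correlation. Of 19 tested cholesterol synthesis genes, 6 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.318). Acat2 and Mvd, which encode enzymes of that pathway, rose 1.30-fold and 1.27-fold.

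Most tested markers of bone and cartilage differentiation were lower with LPS. Of 7 tested osteogenic markers 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone. Bone sialoprotein (Ibsp) fell from 4.05 ± 1.10 to 0.294 ± 0.101 FPKM, alkaline phosphatase (Alpl) from 20.6 ± 3.46 to 6.95 ± 0.885 and the transcription factor Sp7 from 6.27 ± 1.17 to 2.62 ± 0.209. Osteopontin (Spp1), which is also made by activated immune cells, rose from 132 ± 10.9 to 267 ± 19.5 FPKM. camera gave an adjusted p of 0.00913, and an adjusted p of 0.269 with an estimated correlation, and the list did not pass among genes with an FPKM of at least 5 (0.0956). All 4 tested chondrogenic markers, of 10 in the table, fell, also when adjusted over the list alone. Comp was 3.39-fold, Sox6 3.26-fold, Acan 2.96-fold and Sox9 2.42-fold lower, and the list was too short for the set test. Below the filter, Prg4 (0.0778 to 0.359 FPKM), Matn3 and Col10a1 had higher means with LPS, and Col2a1 (0.243 to 0.0458 FPKM), Sox5 and Chad lower ones. Of 6 tested adipogenic markers 4 rose, also when adjusted over the list alone. They were the transcription factors Cebpb (2.69-fold), Cebpd (2.48-fold) and Klf15 (1.87-fold) and the lipase Lpl (1.38-fold), of which Cebpb and Cebpd also act in inflammatory signalling. That list passed camera (adjusted p = 0.0394), with an adjusted p of 0.269 with an estimated correlation, and did not pass without LPS replicate 2 (0.0592). Below the filter and not tested, the adipogenic marker Pparg was lower with LPS (0.95 ± 0.1495 to 0.495 ± 0.0116 FPKM). Adipoq, Fabp4, Lipe and Plin1, also below it, were higher, all at means under 1 FPKM.

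Of 16 tested mesenchymal stem cell markers, 8 rose and 4 fell, and 8 rose and 5 fell when adjusted over the list alone, with an adjusted p of 0.318 by camera. Cxcl12, the chemokine that retains blood stem cells in marrow, rose from 20.4 ± 12.8 to 140 ± 2.2 FPKM, or 6.64-fold, and 10.3-fold without untreated replicate 1. Pdgfra and Nt5e (CD73) rose 2.90-fold and 2.73-fold, and Mcam (CD146) was 1.85-fold lower.

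Markers of other cell types were low. Of 28 myeloid and microglial markers measured, 5 were tested, 0 rose and 1 fell, with 0 either way when adjusted over the list alone. The median FPKM of the 28 was 0.051 in untreated and 0.068 in LPS co-culture. Camera gave the list an adjusted p of 0.906. Tmem119, which is expressed by microglia and by bone-forming cells, stood at 64.7 ± 2.14 and 69.4 ± 1.20 FPKM (adjusted p = 0.413). Lyz2 was 1.73-fold lower (adjusted p = 0.0462), from 1.28 ± 0.230 to 0.764 ± 0.279 FPKM, with the call lost in 11 of 21 alternatives, among them leaving out any library other than LPS replicate 3 (up to 0.142). The single tested endothelial marker, the transcription factor Erg, was 5.50-fold lower, and of the lymphoid and erythroid symbols in the table, 5 in all, 0 reached the filter. Of 13 genes of the mitochondrial genome 3 rose, and 0 when adjusted over the list alone. Mt-nd3, Mt-cyb and Mt-co1 had log2 fold changes of 0.24, 0.20 and 0.15, and their calls were lost in 5, 6 and 7 of 22 alternatives, among them leaving out untreated replicates 2 or 3 or LPS replicates 1 or 2, with adjusted p up to 0.161. That list did not pass camera (adjusted p = 0.185) but passed without untreated replicate 1 (0.0208) and with quantile normalization (0.00518), with an adjusted p of 0.738 with an estimated correlation.

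**Figure D2:**
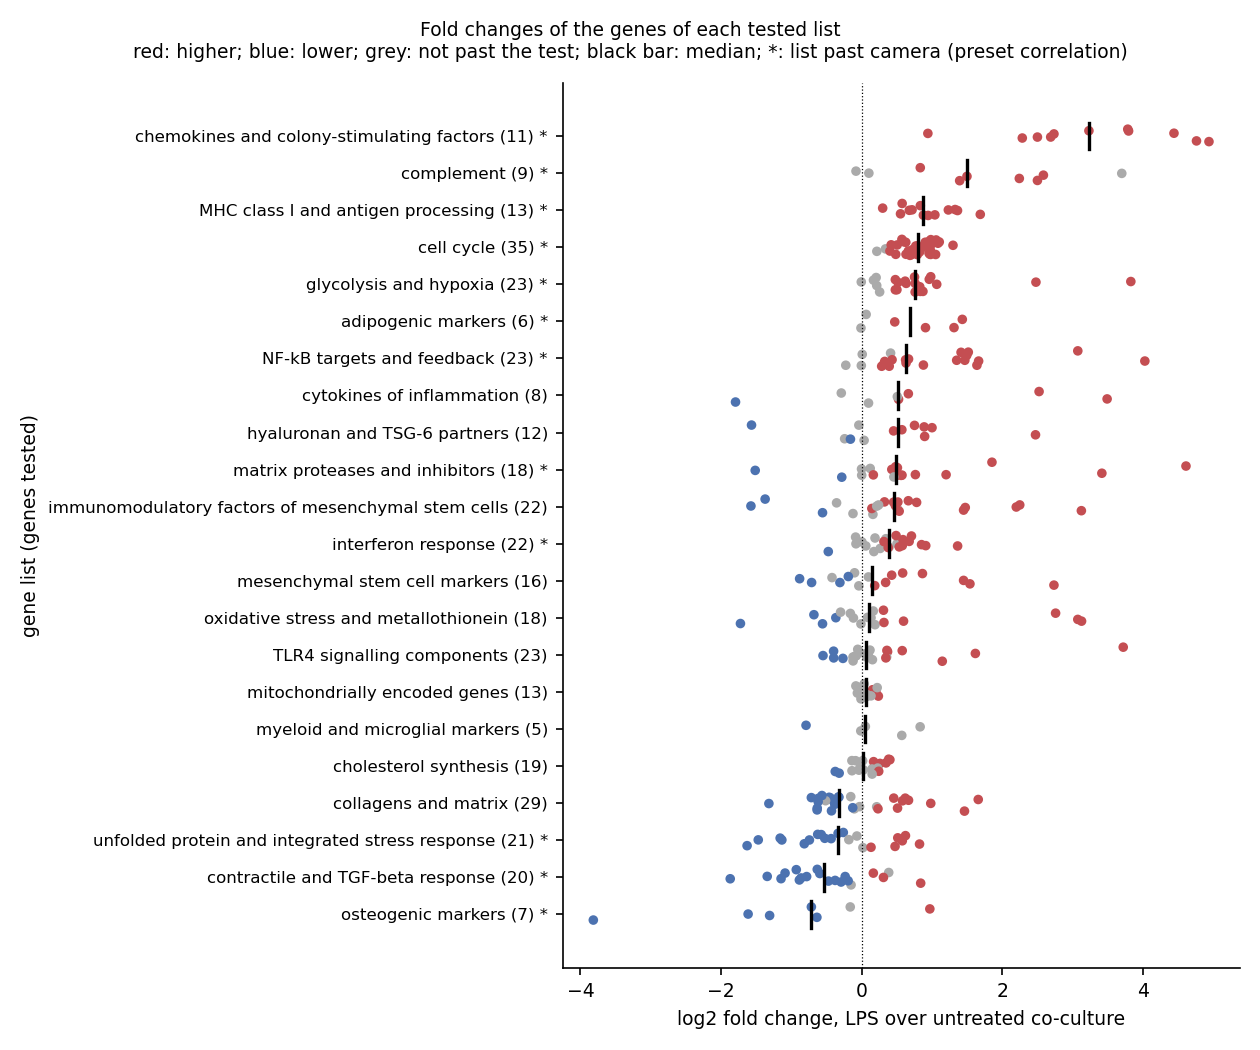
log2 fold change (x axis) of each tested gene in the 22 lists with at least 5 tested members (y axis, number tested in parentheses), coloured by the edgeR call, with a black bar at the median. All 11 chemokine and colony-stimulating factor genes lie to the right of 0 (median 3.23), 33 of 35 cell cycle genes passed as higher (median 0.80), and 15 of 20 contractile genes passed as lower.

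By camera with the preset correlation, 9 lists passed as higher and 3 as lower, and 0 of the 22 lists passed with an estimated correlation. fry, which asks whether a list's genes move one way and compares them with no other genes, passed 17. Median, mean and camera direction had the same sign in all 22 lists.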

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

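The tests with counts divided by 4, protein-coding genes only, camera on the counts and library sizes without the 50 most abundant genes were chosen after the data were seen. limma on log2(FPKM + 1) at a pseudocount of 1 was the design's test for a table without raw counts. It was made an alternative after the table was seen. The other alternatives were planned. The counts of genes higher and lower stayed within 1.5 times 2323 and 2201 in every alternative run except a minimum absolute log2 fold change of 1, which left 300 and 197 and shows the size of the changes, not a different test. The number of gene lists past the set test, 12, went to 0 with the correlation estimated for each list. Leaving out each library in turn gave 1752 to 2635 genes higher, 1640 to 2419 lower, a Tnfaip6 log2 fold change of 0.38 to 0.57 and 12 to 16 lists, and Tnfaip6 stayed past the test in all alternatives run other than that size minimum, which its log2 fold change did not reach, with adjusted p from 7.18e-05 to 0.0283. Of the comparisons of named genes with an alternative, 2333 kept direction and call, 64 lost the call, 9 gained one and 10 turned direction. Of the set tests, 378 kept their call, 15 lost it and 23 gained one.

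The 10 that turned direction concerned 3 genes that were not called in the main test, and the cause was not tested. The log2 fold change of Cd44 became 0.0069 with limma with a trend, without one and with a robust trend, 0.0071 with a pseudocount of 0.1, 0.0064 with a pseudocount of 5 and 0.0028 without untreated replicate 2, with a range from -0.083 to 0.0028 over the left-out libraries. That of Hyal1 became -0.16 without untreated replicate 2, -0.011 without untreated replicate 3 and -0.13 without LPS replicate 2, with a range from -0.16 to 0.32 over the left-out libraries, and that of Tmem119 became -0.031 with quantile normalization. With a block for replicate number, 2160 genes were higher, 2024 lower and 13 lists passed. Deviations of libraries with the same number correlated across genes at 0.036, 0.084 and 0.094, and those with different numbers at -0.099 to 0.017. Each same-number value thus lay above every other, so pairing is not excluded. As none exceeded the limit of 0.1, the numbers were not taken as pairs in the main test. Depth limits genes with few fragments, where 1 fragment was taken to be worth about 4 count units. The fragment numbers and their intervals rest on that assumption and were not computed with another unit.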

Other observations

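The tests of a mixed library by rising genes, of an exchanged label, of microglial RNA and of pathways without the genes of the fixed lists were chosen only after the result was seen, as were the genes named in the next paragraph.

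Some annotated pathways held more called genes than other tested genes did. Over 464 tests of 232 pathways, 38 pathway and direction pairs passed, 23 of them higher and 15 lower, and these include pathways such as cell cycle and glycolysis that overlap the fixed lists. With the genes of the fixed lists left out, 30 of 460 pairs passed, 18 higher and 12 lower. The following counts leave those genes out. By Fisher's exact test, the smallest adjusted p were those of cytoskeleton in muscle cells (45 of 96 lower, 1.27e-07) and cytokine-cytokine receptor interaction (38 of 67 higher, 4.73e-07). Axon guidance genes fell in 33 of 109 cases (adjusted p = 4.58e-02 by the same test), against 18.9% in the background. Another 25 rose (22.9%), near the background of 23.0%. Those that fell included the netrin receptor Unc5c, from 3.00 ± 0.244 to 1.11 ± 0.101 FPKM (SD, n = 3), the Slit receptor Robo2 and the ephrin receptor Epha4. Their log2 fold changes were -1.49, -1.31 and -1.30. Hippo signalling genes fell in 37 of 100 cases (adjusted p = 1.28e-03), among them the Wnt receptor Fzd8 from 16.4 ± 4.27 to 4.23 ± 0.240 FPKM and the mesenchymal transcription factor Snai2 from 29.1 ± 3.07 to 14.9 ± 0.592. DNA replication genes rose in 14 of 27 cases (adjusted p = 2.53e-02) against 23.0% in the background. Pentose phosphate pathway genes, several of which also belong to glycolysis, rose in 10 of 18 cases (adjusted p = 4.70e-02), including H6pd at 1.66-fold. Fisher's exact test treats genes as independent, which genes of a pathway are not.

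Untreated replicate 1 lay between the other untreated libraries and the LPS libraries. If RNA or reads of an LPS library had been mixed into it, genes would stand at a single share of the way to the LPS level. Among 67 rising genes the median share was 20.6%, with quartiles of 14.4% and 28.0%. Of these genes 28.4% lay more than 3 standard errors from that median. Those errors rest in part on the spread of the few other untreated libraries, so this percentage cannot decide. The 22 falling genes had a median of 47.0%, with quartiles of 41.0% and 53.9%, apart from those of the rising genes. That difference argues against a single mixture as the whole cause, and the share of 20.6% argues against an exchanged label. The 33 called cell cycle genes stood at a median of -18.5% of the way (quartiles -35.0% and -9.3%), away from LPS, so a response of the whole program in that library is argued against too, and what set it apart stays open.

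Genes of inflammation and of the cell cycle were higher together, and RNA of the co-cultured microglial line could be a source. Of 28 measured myeloid markers, 4 reached a mean FPKM of 1 with LPS and 4 without, while the median rise of cell cycle genes was 6.2 FPKM. Only 5 of the 28 could be tested, and Adgre1, below the filter, went from 0.0453 ± 0.0414 to 0.329 ± 0.0161 FPKM (SD, n = 3). Among the abundant ones were Tmem119 at 64.7 and 69.4 FPKM and Fcer1g at 5.95 ± 4.31 and 10.9 ± 14.3 FPKM (SD, n = 3), untreated first. How well mouse reads align to the rat build was not measured and may differ between genes, so low markers do not exclude microglial RNA, which stays open.

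Collagens and other abundant genes took less of the counts with LPS, which could raise the remaining genes. With library sizes that leave out the 50 most abundant genes, the median log2 fold change of the cell cycle list was 0.769, against 0.799, with 33 members past the test, and that of the glycolysis and hypoxia list was 0.72 with 18 members past it. This test could hardly have come out otherwise. The main test already used trimmed-mean factors, and the median shift over all genes between the settings was -0.03. The 50 genes took 32.2% ± 0.588 of the counts in untreated and 28.1% ± 0.388 in LPS co-culture (SD, n = 3). A change of that size is too small to give a median of 0.799. The size of the change, rather than the test, argues against that share as the cause.

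The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split called 4524 genes and the highest other 2, so 1 of the 10 splits reached the real count. Every other split mixes untreated and LPS libraries, so the LPS difference widens the spread within its groups and lowers its calls. Those counts are therefore not a level that chance alone would give. For gene lists past the set test the real split gave 12 and the highest other 14, so 4 of the 10 splits reached the real number, and the other splits that did so put untreated replicate 1 with a pair of LPS libraries.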
